A study of Mus musculus with 18 samples.

How the data were processed

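The values used are the authors' deposited counts, in raw reads, given per gene and library in columns split by the number of T positions in a read (0 to 20) and the number of T-to-C conversions (0 to 3). That meaning of the columns was inferred from their headings and values: 0 reads fell in columns with more conversions than T positions. Per the submitters' processing notes, reads were aligned with Bowtie 0.12.8 to mm10. The counting program, gene annotation, permitted mismatches and region counted per gene are not given in the sources used here. Per the labels, cells received 200 µM 4sU, about 10% of each lysate was saved as input, and the rest was digested with RNase I and monosomes taken from a sucrose gradient. Input was fragmented by alkali, both materials were selected at 25 to 35 nt and depleted of ribosomal RNA, and 4sU was converted with NaIO4. A 4sU-labelled spike-in was added, and its counts were not used here. All 18 libraries were used, with 6230562 to 87536081 reads each, and the 95% Wilson interval of the converted share in the smallest library was 8.05% to 8.09%.

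Footprints were compared with input by edgeR quasi-likelihood fits with a term for labelling time, TMM scaling and edgeR's filter for low counts. Input and footprint slopes used hours of 4sU as a number, and the change of the ratio used the product of material and hours over all 18 libraries. Conversion in footprints against input used edgeR's design for methylation counts, with converted and unconverted reads as a pair of columns per library, over the 16 labelled libraries. The relative labelling of each input gene was the log2 odds of conversion minus the library median, tested against 0 by limma. No background was subtracted from it, and the T content of the reads also enters. Conversion fits kept genes with a mean of at least 50 reads per library and at least 50 converted reads in all, and log odds used a pseudocount of 0.5. All p-values were two-sided, and Benjamini-Hochberg adjusted p under 0.05 was the call. Gene lists were tested by camera with a correlation of 0.01 and at least 3 members, adjusted over the lists of each comparison. Library-level tests were exact sign flips or permutations, with 1e+05 random permutations where the full set was too large. Shares carry 95% Wilson intervals. The lag was read by linear interpolation of input shares in experiment 1 after subtraction of the unlabelled share of the same material.

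The comparisons, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. Under that rule each gene-wise comparison names, among genes past the call with a mean of at least 100 reads per library (50 for conversion fits), the 8 highest and 8 lowest log2 values, and of each list up to 4 members with the smallest adjusted p. For footprints against input a gene also needed the same direction in every lysate. RIKEN clones, predicted genes (Gm plus digits) and pseudogenes (-ps) were counted and not named, and not all genes that qualify are named in the text. Rpsa, Pabpc1, Fth1 and Gnai2 in the conversion comparison, and the genes of the ratio trend, were named after their values were seen. The 20 lists were cytosolic ribosomal proteins, other terminal oligopyrimidine mRNAs, immediate-early regulators, inflammatory genes, interferon response, macrophage and lysosome, markers of other cell types, upstream open reading frames, ATF4 targets, p53 targets, mitochondrially encoded mRNAs, nuclear oxidative phosphorylation, glycolysis, replication-dependent histones, endoplasmic reticulum chaperones, heat-shock proteins, cholesterol synthesis, proteasome, mitotic genes and noncoding RNAs, all written from general knowledge.

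The pairing of input and footprints by lysate comes from the protocol text in the labels. After removal of the material means, input and footprint profiles of 1 lysate correlated at 0.113 to 0.674, and 3 of 9 lysates correlated best with their own partner. The differences between the experiments at 20 and 40 min correlated at r = 0.781 in input and 0.732 in footprints across genes. With lysate as a replicate block 7979 genes differed between footprints and input, against 7699. The first principal component held 70.4% of the variance and parted the materials, and the second held 12.2%.

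Alternatives tried were DESeq2 size factors, DESeq2's Wald test, no low-count filter, experiment or lysate as a replicate block, experiment 1 alone, leaving out single lysates, leaving out mitochondrially encoded, histone and noncoding genes, the other way of background subtraction, the median over genes, a mean of at least 200 reads, limma on the log odds, a pseudocount of 2 and camera's estimated correlation. For conversion, each labelled lysate was left out in turn. For the fits of read counts, only the 0, 20, 40 and 120 min lysates were left out, and those of 30, 60 and 90 min never were. Added once results were known were experiment 2 alone, conversion relative to the library-wide share, reads with at least 2 conversions, these last 2 together, conversions per T position and the labelled share of a binomial mixture. The fits were tested on simulated data with 100 changed genes per effect. At log2 effects of 0.5 and 1, those recovered were 59 and 94 for footprints against input, 35 and 89 for input slopes, 64 and 98 for footprint slopes, 9 and 79 for the ratio trend, 2 and 29 for conversion and 28 and 99 for relative labelling. Between 3 and 12 unchanged genes were called. For relative labelling the simulated noise had a set SD of 0.5 and was not fitted to the data. For conversion the simulated libraries held no library-wide difference between the materials, unlike the real ones. Recovery in these 2 real fits may thus differ. The mixture's largest error was 1.87%, for the 60 min input library. Its error at labelled shares as low as the 0.048% fitted in 20 min footprints of experiment 2 is not given. A simulated delay of 15 min came back as 14.3 to 14.8 min. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.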

Results

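Reads per gene were counted in cytoplasmic input RNA and in ribosome footprints of RAW264.7 cells, a mouse macrophage-like line, after labelling with 4-thiouridine (4sU), a uridine analogue that enters newly made RNA. The 18 libraries came from 9 lysates, each giving 1 input and 1 footprint library. Experiment 1 had 6 lysates, labelled for 0, 20, 40, 60, 90 and 120 min, and experiment 2 had 3, labelled for 20, 30 and 40 min. The 20 and 40 min times thus had 2 lysates each and every other time had 1, and the unlabelled lysate belonged to experiment 1. Input libraries held 6230562 to 7933796 reads in experiment 1 and 26359243 to 48139330 in experiment 2, and footprint libraries 11771175 to 23327760 and 29065324 to 87536081. Of 14002 genes listed in any library, 10181 were listed in every library. The p-values measure only the spread between these samples, since the labels do not state whether the lysates are separate cultures.

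The first question, taken from the series' stated purpose of measuring ribosome density on nascent mRNAs, was how newly made mRNA appeared in the cytoplasm and on ribosomes over time. A read counted as converted when it held at least 1 T-to-C conversion, the trace of 4sU after chemical conversion. In input the converted share rose from 0.289% of reads without label (95% Wilson interval 0.284 to 0.293) to 8.07% at 120 min (8.05 to 8.09). In footprints it rose from 0.298% (0.295 to 0.2999) to 5.54% (5.53 to 5.55), and these intervals cover counting error only. At 20 min the share was 0.840% ± 0.0372 (SD, n = 2) in input and 0.385% ± 0.102 (SD, n = 2) in footprints. At 40 min it was 2.07% ± 0.122 (SD, n = 2) in input and 1.08% ± 0.293 (SD, n = 2) in footprints. Over 9 libraries the share correlated with minutes of 4sU with r = 0.990 in input and r = 0.977 in footprints, each with a two-sided permutation p = 1e-05, the smallest the draws can give. Spearman's rho was 0.992 in both, with a permutation p = 2e-05. Benjamini-Hochberg adjustment over the family of 6 relations gave 3e-05 for r and 6e-05 for rho. Without the 2 libraries farthest from the median time, r was 0.966 and 0.881 (exact p = 0.00159 each) and rho 0.982 in both. Within experiment 1, r was 0.991 and 0.988 over 6 libraries (exact p = 0.00139 each) and rho was 1, while experiment 2 holds too few libraries for a value.

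The next question was whether newly made mRNA is represented on ribosomes as in the cytoplasm. In each of the 8 labelled lysates the footprints held a smaller converted share than the input of the same lysate. The log2 odds ratio of conversion, footprint against input, averaged -0.97 ± 0.46 (SD, n = 8) and ranged from -1.80 to -0.40, with an exact two-sided sign-flip p = 0.00781, the smallest that 8 lysates allow. The unlabelled lysate gave 0.05. The mean was -0.67 ± 0.20 (SD, n = 5) in experiment 1 and -1.46 ± 0.30 (SD, n = 3) in experiment 2. The log2 odds ratio lay nearer 0 at later times, with r = 0.70 (exact two-sided p = 0.0537, adjusted 0.0805) and rho = 0.82 (exact p = 0.0175, adjusted 0.0175) over 8 lysates. Without the 2 lysates farthest from the median time, r was 0.51 (exact p = 0.306) and rho 0.62 (exact p = 0.244), still positive but past no threshold over 6 lysates. Within experiment 1 the values were r = 0.82 and rho = 0.9 over 5 lysates, given without a test. Experiment 2 holds only times of 20 to 40 min, so experiment and time are partly confounded and the p-values over 8 lysates ignore this. From the median over genes rho was 0.57 (exact p = 0.152). The test of r passed without the 20 min lysate of experiment 1 (r = 0.76, exact p = 0.0413, n = 7) and without the 30 min lysate (r = 0.76, exact p = 0.0492, n = 7). That of rho no longer passed without the 40, 60, 90 or 120 min lysate of experiment 1 (rho = 0.76, 0.73, 0.76 and 0.76, exact p = 0.0571, 0.073, 0.0603 and 0.0603, n = 7). In experiment 1, after subtraction of the unlabelled share, the footprints reached the share that input had reached 14.5 min earlier at 20 min of labelling. The lag was 13.6 min at 40 min, 16.99 min at 60 min, 28.1 min at 90 min and 26.5 min at 120 min, values with no test because each time had 1 library per material. The late values depend on the measure: at 90 and 120 min they were 19.7 and 18.8 min from the median over genes and 17.4 and 22.2 min from the labelled share of the mixture, but 35.2 and 31.7 min from reads with at least 2 conversions and 30.6 and 26.4 min from conversions per T position. Without the 60 min lysate the value at 90 min was 19.9 min, and without the 90 min lysate that at 120 min was 36.6 min.

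**Figure D1:**
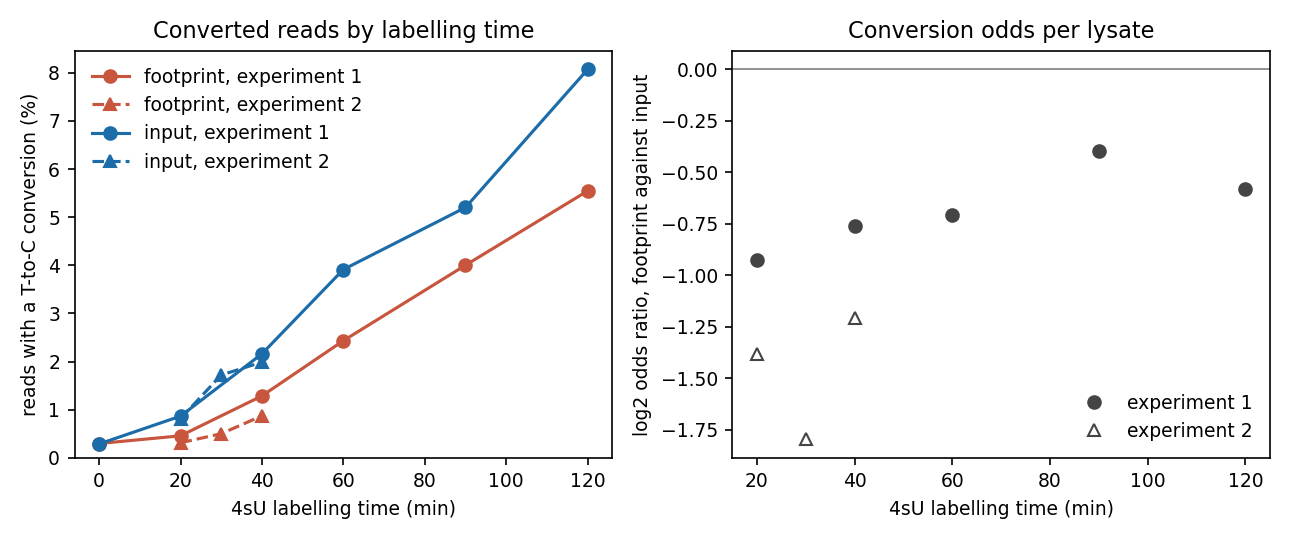
Left, share of reads with a T-to-C conversion (%) against 4sU labelling time (min), 1 point per library, in input and footprints of experiments 1 and 2. Right, log2 odds ratio of conversion (footprint against input) per labelled lysate, all 8 between -1.80 and -0.40.

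Which genes carry more or fewer ribosome footprints per input read was asked next, over all lysates. Macrophage and lysosome genes were denser in footprints than in input, with 33 of 39 measured members higher and 4 lower. Among them were Fcer1g, the shared signalling chain of Fc receptors (log2 1.99, adjusted p = 2.4e-11), and Cd68, a lysosomal glycoprotein (1.26, adjusted p = 1.72e-10). The mRNAs known for upstream open reading frames were sparser, with 3 of 19 higher and 14 lower. Atf4, the transcription factor of the integrated stress response, fell by 2.43 on the log2 scale (SE 0.0921, adjusted p = 6.72e-12), from a mean of 347 normalised CPM in input to 64.6 in footprints over 9 lysates. Ibtk was at -1.62 and Odc1, the first enzyme of polyamine synthesis, at -1.23, while Eif1, the start-codon selection factor, was at 3.34. Atf4 (ENSMUSG00000042406) lies on chromosome 15, 80255184 to 80257541, in build GRCm38.

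By edgeR with Benjamini-Hochberg adjustment at 0.05, 3618 of 10110 genes were higher and 4081 lower in footprints, of which 892 were at least 2-fold higher and 1731 at least 2-fold lower. At the top stood Atp6v0c, the proton-pore subunit of the vacuolar ATPase (ENSMUSG00000024121, chromosome 17, 24163866 to 24169702), at 4.66 (SE 0.28, adjusted p = 8.32e-10). Its level was 14.02 ± 6.7 normalised CPM in input and 368 ± 93.7 in footprints (SD, n = 9). The histone gene Hist1h4n was at 4.29 and the calcium-binding protein gene S100a11 at 4.20. At the other end stood Aoc2, an amine oxidase (ENSMUSG00000078651, chromosome 11, 101325063 to 101329702), at -6.18 (SE 0.242, adjusted p = 8.73e-12). Its mean level was only 0.123 normalised CPM in footprints. The kinase Map3k10 was at -6.11 (0.311 normalised CPM in footprints), Dst, a giant cytoskeletal linker, at -4.23 and the kinase Tesk1 at -4.08. Each of these genes had the same direction in 9 of 9 lysates. Map3k10 overlaps Ttc9b and Tesk1 overlaps Cd72 in the annotation, Atp6v0c has 2 named pseudogenes, S100a11 has 1 and histone genes are near-identical copies, so these values are uncertain. The same limit holds for other genes named for their density: Eif1 has 3 named pseudogenes, Ldha 2 and Rps29 and Rplp1 1 each, while Pdia3 overlaps Catsper2, Ube2c overlaps Tnnc2 and Shmt2 overlaps Ndufa4l2. The region counted per gene is not given in the sources used here. The sizes for Aoc2 and Map3k10 also rest on few footprint reads.

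Nuclear-encoded oxidative phosphorylation genes were higher in footprints in 56 of 74 cases and lower in 3, with a median of 0.53 and Atp5g3, an ATP synthase subunit, at 1.66. Of the 13 mitochondrially encoded mRNAs, 0 were higher and 7 lower, with a median of -1.45, mt-Co3 at -3.36 and mt-Co1 at -2.81, both cytochrome c oxidase subunits. Footprints of mt-Co3 varied widely, at 782 ± 454 normalised CPM against 6779 ± 983 in input (SD, n = 9). How far the monosome fraction recovers ribosomes of mitochondria was not tested, so these values may not be ribosome density. Glycolysis genes were higher in 17 of 20 cases and lower in 1, with Gapdh at 1.84 (it overlaps Iffo1 and has 2 named pseudogenes) and Ldha at 0.94. Proteasome subunits were higher in 29 of 34 cases and lower in 0, with Psmb2 at 1.06, and heat-shock proteins in 10 of 13 and 0, with the chaperone Hsp90ab1 at 2.13. Histone genes were higher in 40 of 51 cases and lower in 1, with Hist1h2bc at 2.57. Camera with a correlation of 0.01 called the oxidative phosphorylation and histone lists (adjusted p = 5.24e-07 each), glycolysis (0.000237), proteasome (0.000116), heat-shock (0.00407), macrophage (6.99e-07) and upstream-frame lists (0.0025), the last downward. With an estimated correlation these calls were lost, at adjusted p = 0.493 with an estimated correlation for oxidative phosphorylation and histones and adjusted p = 0.332 with an estimated correlation for glycolysis, proteasome and heat shock. The macrophage list gave adjusted p = 0.12 with an estimated correlation and the upstream-frame list adjusted p = 0.0935 with an estimated correlation. The mitochondrially encoded list was not called (adjusted p = 0.183).

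Genes of the translation machinery did not move as a block. Cytosolic ribosomal protein genes were higher in 30 of 76 cases and lower in 11 (median 0.09, and -0.06 in experiment 1 alone), with Rps29 at 1.26, Rplp1 at -1.97 and Rpl41 at -2.69, and camera did not call the list (adjusted p = 0.0585). Other terminal oligopyrimidine mRNAs, which share their growth-regulated translation, were higher in 15 of 21 cases and lower in 1, with the histone chaperone Nap1l1 at 1.70 (camera adjusted p = 0.000818, adjusted p = 0.332 with an estimated correlation). ATF4 targets were higher in 20 of 28 cases and lower in 1, with the serine hydroxymethyltransferase Shmt2 at 1.21 (camera adjusted p = 0.0025, adjusted p = 0.332 with an estimated correlation). Cholesterol synthesis genes were higher in 16 of 22 cases and lower in 4, with the isomerase Idi1 at 1.24 and the sterol sensor Insig1 at -1.29 (camera adjusted p = 0.0162, adjusted p = 0.332 with an estimated correlation). Immediate-early regulators were higher in 19 of 42 cases and lower in 5, with Myc at 2.63 and Jund at -2.13 (camera adjusted p = 0.0305, adjusted p = 0.602 with an estimated correlation). Myc had only 0.673 ± 0.637 normalised CPM in input (SD, n = 9), so its size is uncertain. Mitotic genes were higher in 14 of 26 cases and lower in 6, with the ubiquitin-conjugating enzyme Ube2c at 1.29 and the proliferation marker Mki67 at -1.47 (camera adjusted p = 0.0317, adjusted p = 0.454 with an estimated correlation).

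Camera called none of the inflammatory (11 of 30 higher and 6 lower, adjusted p = 0.289), interferon (13 of 26 higher and 1 lower, adjusted p = 0.0541), endoplasmic reticulum chaperone (12 of 20 higher and 3 lower, adjusted p = 0.0716) and p53 lists (4 of 20 higher and 7 lower, adjusted p = 0.581). Their members included the adhesion molecule Icam1 at 0.66, the apoptosis inhibitor Birc3 at -0.89, the antiviral gene Bst2 at 1.28, the disulfide isomerase Pdia3 at 2.34, Edem1 of protein quality control at -1.84, the cell-cycle inhibitor Cdkn1a at 3.21 and Ei24 at -2.08. The p53 list's median of -0.05 turned to 0.01 with DESeq2 size factors. Of 33 markers of other cell types, 14 were listed in any library and 1 could be tested, the B-cell receptor component Cd79b, at 0.68 (adjusted p = 0.0626). Cd79b passed with experiment or lysate as a replicate block (0.81 and 0.82, adjusted p = 0.000165 and 0.000342) and without the 20 min (0.73 and 0.77, adjusted p = 0.0308 and 0.0413) or 40 min lysate (0.69 and 0.73, adjusted p = 0.025 and 0.0392) of experiment 1 or 2. It also passed with DESeq2 size factors (adjusted p = 0.0475), without a low-count filter (0.046), with DESeq2's Wald test (0.0479) and in experiment 2 alone (0.00671). None of 33 noncoding RNAs was listed in any library. Counts adjusted over the list alone were equal except for 18 higher and 5 lower immediate-early genes, 10 higher and 6 lower inflammatory genes and 1 higher marker of other cell types.

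**Figure D2:**
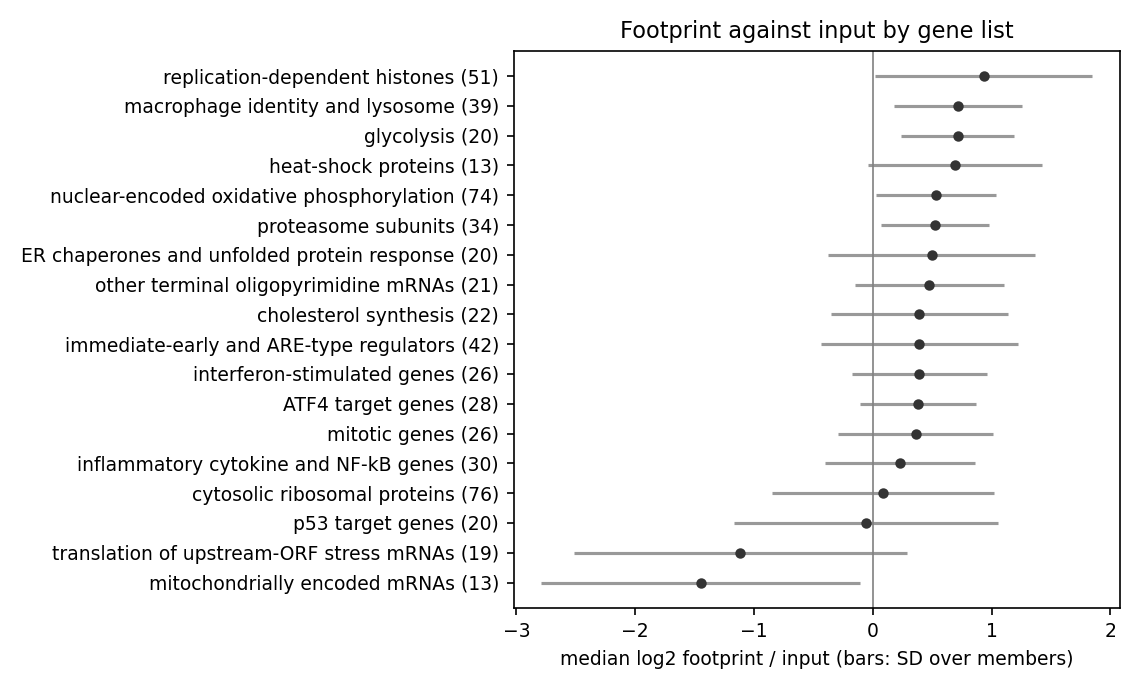
Median log2 footprint against input per gene list (x axis), with bars for the SD over members and the number of measured members in parentheses. Histone genes have the highest median (0.93) and mitochondrially encoded mRNAs the lowest (-1.45); the p53 list's -0.05 turns to 0.01 with DESeq2 size factors and the ribosomal protein list's 0.09 to -0.06 in experiment 1 alone.

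Which mRNAs turn over fastest was asked from the converted share of each gene in the 8 labelled input libraries, relative to the library median. Inflammatory, immediate-early and mitochondrially encoded mRNAs were among the most labelled. Tnf, the tumour necrosis factor gene (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007), stood 4.77 above the median on the log2 odds scale (SE 0.177, adjusted p = 3.77e-09). Its converted share was 0.261% without label and 65.3% at 120 min. Rgs1, a regulator of G-protein signalling, stood at 5.08, Txnip, a thioredoxin inhibitor, at 4.54 and the transcription factor Klf10 at 4.25. Lcmt2 was at 4.59, but it overlaps Adal and held 6.02% converted reads without label, against 0.289% in the library, so this value is uncertain. No background was subtracted for any of these values. Least labelled were Col4a5, a collagen chain, at -2.53, the RNA-binding protein gene Ybx1 at -2.31 and Edf1 at -2.28. Col4a5 lay near the background, with 0.139% to 0.915% converted reads in labelled input against 0.171% without label.

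By limma with Benjamini-Hochberg adjustment, 2481 of 7045 genes were above and 2480 below the library median. Of the immediate-early regulators 33 of 34 were above and 0 below (median 3.35, camera adjusted p = 6.87e-16, adjusted p = 0.0633 with an estimated correlation). Of the inflammatory genes 18 of 22 were above and 1 below (median 2.50, camera adjusted p = 6.23e-07, adjusted p = 0.112 with an estimated correlation). All 13 mitochondrially encoded mRNAs were above, with mt-Nd3, a complex I subunit, at 4.06 (median 3.37, camera adjusted p = 1.43e-09, adjusted p = 0.274 with an estimated correlation). All 51 histone genes were above, with Hist2h4 at 2.38 (median 1.83, camera adjusted p = 6.87e-16, adjusted p = 0.274 with an estimated correlation). The p53 list (11 of 14 above and 2 below), the upstream-frame list (13 of 18 above and 1 below) and the interferon list (5 of 6 above and 1 below) had camera adjusted p = 0.00462, 0.00105 and 0.039, each with adjusted p = 0.223 with an estimated correlation. Of the interferon genes, Trim25 held 6% converted reads in unlabelled input, while Rtp4 and Ifi47 held 0%.

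Housekeeping mRNAs were little labelled. Ribosomal protein genes were below the median in 64 of 71 cases and above in 0, with Rpl36 at -1.71, which has 9 named pseudogenes (camera adjusted p = 2.6e-11, adjusted p = 0.359 with an estimated correlation). Oxidative phosphorylation genes were below in 63 of 73 cases, or 64 adjusted over the list alone, with Uqcrc1, a complex III subunit, at -1.72 (camera adjusted p = 2.28e-11, adjusted p = 0.291 with an estimated correlation). Macrophage and lysosome genes were below in 29 of 36 cases and above in 4, with the lysosomal protease Ctsa, which overlaps Neurl2 and Pltp, at -1.75 (camera adjusted p = 6.53e-06, adjusted p = 0.352 with an estimated correlation). Proteasome subunits were below in 30 of 33 cases, other terminal oligopyrimidine mRNAs in 19 of 21 and glycolysis genes in 13 of 18 with 3 above. Their camera adjusted p was 1.24e-07, 2.06e-05 and 0.00431, with adjusted p = 0.274, adjusted p = 0.352 and adjusted p = 0.359 with an estimated correlation. For the other lists, too, the counts adjusted over the list alone were equal to those over all genes. The count of reads with at least 2 conversions left 2418 genes to test, of which 848 were above and 872 below.

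**Figure D3:**
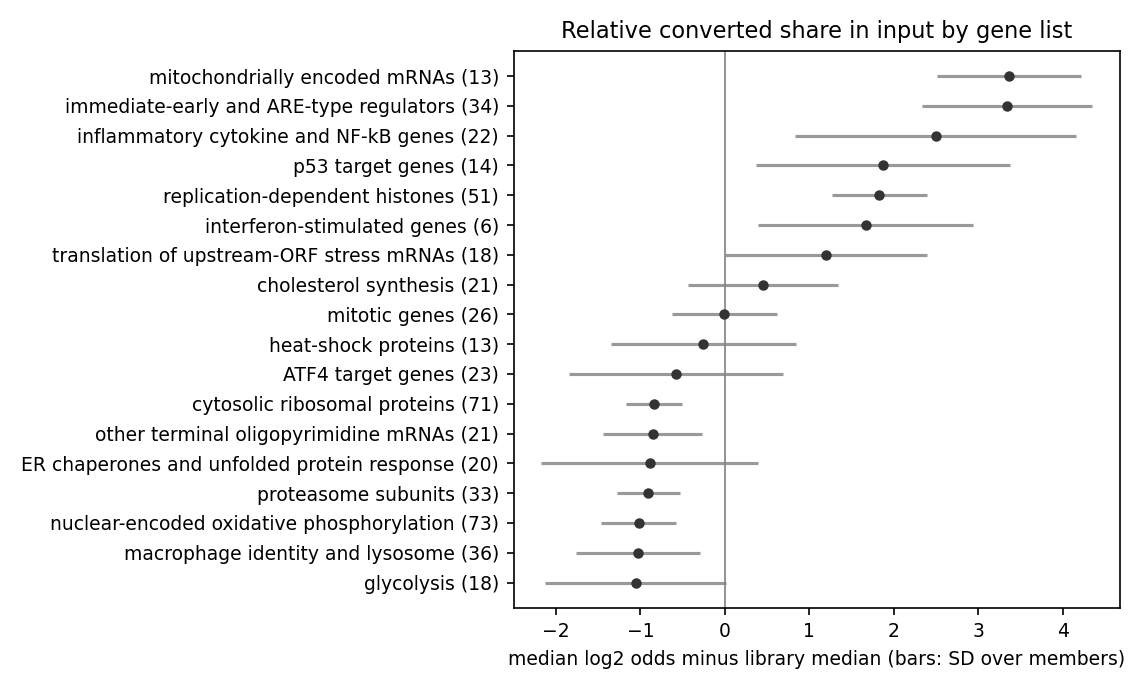
Median log2 odds of conversion in input minus the library median per gene list (x axis), with bars for the SD over members and the number of measured members in parentheses. Mitochondrially encoded mRNAs (3.37) and immediate-early regulators (3.35) stand highest, and glycolysis genes (-1.06) lowest.

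Gene by gene, the lower converted share on ribosomes was asked again in the 16 labelled libraries. Taf15, which encodes an RNA-binding protein, held 0.566% converted reads in footprints and 2.43% in input on average over the 8 lysates (log2 odds -2.34, SE 0.297, adjusted p = 9.42e-13), and Hnrnpa1, which encodes another, was at -1.48. Hnrnph3 was at -2.48, though it overlaps Rufy2. The macrophage pore-forming protein gene Mpeg1 was at -1.72, the lipopolysaccharide receptor gene Cd14 at -1.15, the cyclin Ccnl1 at -1.61, the ribosomal protein gene Rpl10a at -1.45, mt-Nd1 at -0.92 and Nfkb1 at -0.86, where Rpl10a has 3 named pseudogenes. Each of these was lower in 8 of 8 lysates.

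By edgeR with Benjamini-Hochberg adjustment, 4912 of 8276 genes had a lower converted share in footprints and 12 a higher one, with a median log2 odds of -0.79. The share of passing members was largest in the proteasome (33 of 34 lower), mitotic (24 of 26) and mitochondrially encoded lists (12 of 13, or 13 adjusted over the list alone). Ribosomal protein genes were lower in 49 of 71 cases (52 adjusted over the list alone) and higher in 1, and oxidative phosphorylation genes lower in 56 of 74. Immediate-early regulators were lower in 10 of 38 cases (3 adjusted over the list alone) and histone genes in 21 of 51 (20 adjusted over the list alone). Camera, which compares a list with all other genes, put these last lists upward although their medians were negative, at -0.55 (adjusted p = 0.00167) and -0.45 (adjusted p = 0.00674), each with adjusted p = 0.964 with an estimated correlation. Experiment 1 alone gave 1991 lower and 30 higher genes of 7305, and reads with at least 2 conversions gave 2290 lower and 0 higher of 4125. All these counts are unscaled. Relative to the library-wide share, 836 genes were higher and 268 lower. With that scaling and at least 2 conversions, 12 of 13 mitochondrially encoded mRNAs were higher and 0 lower. Of mitotic genes 2 of 26 were higher and 2 lower, and of proteasome subunits 0 of 31 and 1.

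Of the 12 genes with a higher share in footprints, 4 were named after their values were seen. Rpsa, the laminin receptor and small-subunit protein gene (ENSMUSG00000032518, chromosome 9, 120127689 to 120132369), held 2.66% converted reads in footprints and 1.40% in input (log2 odds 0.53, adjusted p = 0.00503), though it was lower in 3 of 8 lysates and has 9 named pseudogenes, which leaves its values uncertain. Pabpc1, which encodes the cytoplasmic poly(A)-binding protein (ENSMUSG00000022283, chromosome 15, 36595661 to 36609668), held 3.46% and 1.41% (0.46, adjusted p = 0.0307) and was lower in 4 of 8. The ferritin heavy chain gene Fth1 was at 0.56 (adjusted p = 0.00489) and Gnai2 at 0.51 (adjusted p = 0.0209). None of the 4 passed with limma on the log odds (adjusted p = 0.104, 0.333, 0.0721 and 0.0579), although the estimates were similar at 0.53, 0.40, 0.55 and 0.50. In experiment 2 alone Rpsa was at -0.13 (adjusted p = 0.546), Pabpc1 at -0.62 (adjusted p = 0.01), Fth1 at 0.19 (adjusted p = 0.413) and Gnai2 at 0.53 (adjusted p = 0.0543). Pabpc1 lost the call without the 40, 60, 90 or 120 min lysate of experiment 1 (adjusted p = 0.0927, 0.226, 0.639 and 0.231, with log2 odds of 0.40, 0.28, 0.21 and 0.28). Gnai2 lost it without the 20 min lysate of experiment 1 or 2 (adjusted p = 0.0549 and 0.0528). With at least 2 conversions per read none of the 4 passed, with Rpsa at 0.05 (adjusted p = 0.923), Fth1 at 0.24 (adjusted p = 0.593), Pabpc1 at -0.07 (adjusted p = 0.852) and Gnai2 at -0.55 (adjusted p = 0.313). The other 8 were Clip1, Mcph1, Nab1, Xxylt1, Gtf2i, Tmem8, Gpn2 at 1.19 and AC155163.2 at 2.13.

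Whether mRNA levels change during labelling was asked from the slope of each gene's input reads with hours of 4sU. With TMM scaling and no use of the spike-in, these levels are relative to other genes. A fall of some mRNAs can thus appear as a rise of others. Among the falling genes was Map3k1, a kinase of the JNK pathway (ENSMUSG00000021754, chromosome 13, 111746428 to 111808993), with a slope of -1.52 log2 per hour (SE 0.272, adjusted p = 0.014). Dusp6, a phosphatase that switches off ERK, was at -1.23, Pcf11, a factor for cutting mRNA 3' ends, at -1.20, the immediate-early gene Fos at -0.83, the p53 inhibitor gene Mdm2 at -0.78 and the survival gene Mcl1 at -0.43. Herpud1, of endoplasmic reticulum quality control, fell too, at -0.65, as did Birc3 at -0.46. Among rising genes were Taf1d at 0.53, which overlaps Cep295, Rps29 at 0.36 and the proteasome gene Psma6 at 0.34.

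By edgeR with Benjamini-Hochberg adjustment over 9 input libraries, 44 of 9269 genes rose and 603 fell. Without the 120 min lysate the count was 0 (953 at unadjusted p under 0.05), every gene named here lost the call (adjusted p from 0.197 to 0.454), and without the 20 min lysate of experiment 2 it was 411. The slopes themselves kept their direction without the 120 min lysate, with Map3k1 at -1.29, Dusp6 at -1.20, Fos at -1.20, Mcl1 at -0.48 and Taf1d at 0.38. Fos also lost the call without the 20 min lysate of experiment 1 or 2 (adjusted p = 0.077 and 0.0801), without the 40 min lysate of experiment 2 (0.0724), in experiment 1 alone (0.0706), with DESeq2 size factors (0.0534) and without the low-count filter (0.0587). Herpud1 lost it without the 20 min lysate of experiment 2 (0.0737) and without the low-count filter (0.0524). DESeq2 called 1309 genes and a model with experiment as a term 1540. Of the immediate-early regulators 0 of 30 rose and 5 fell, or 18 adjusted over the list alone (median -0.59, camera adjusted p = 1.74e-08, adjusted p = 0.379 with an estimated correlation). Of the inflammatory genes 0 of 26 rose and 2 fell, or 5 adjusted over the list alone (camera adjusted p = 0.0245, adjusted p = 0.398 with an estimated correlation). Camera also called small shifts upward of lists in which few members passed. Ribosomal protein genes had a median of 0.27 with 2 of 73 passing (1 adjusted over the list alone; camera adjusted p = 7.4e-17, adjusted p = 0.398 with an estimated correlation), and oxidative phosphorylation genes 0.24 with 0 of 74 (5.17e-14, adjusted p = 0.398 with an estimated correlation). The proteasome list had 0.19 with 1 of 34 (camera adjusted p = 6.26e-07, adjusted p = 0.358 with an estimated correlation) and the macrophage list 0.15 with 2 of 39 (1.17e-05, adjusted p = 0.358 with an estimated correlation). Median and mean differed in sign for the ATF4 (0.05 and -0.03), glycolysis (0.10 and -0.04) and cholesterol lists (0.01 and -0.04), none of which camera called.

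The same question, with the same limit to relative levels, was asked of footprints. Pabpc1 fell by 1.51 log2 per hour (SE 0.182, adjusted p = 0.000803), from 736 to 149 normalised CPM between 0 and 120 min of experiment 1. The amino acid transporter Slc38a2 was at -1.33 (adjusted p = 0.000118), Map3k1 at -1.44 (0.000515), the cell-cycle phosphatase Cdc25a at -1.36, Ccnl1 at -1.01, Rpsa at -0.71 (0.000515) and the chaperone Hspa8 at -0.42. The mitochondrially encoded ATP synthase genes mt-Atp8 (chromosome M, 7766 to 7969) and mt-Atp6, which overlap, rose at 1.45 (adjusted p = 0.00123) and 1.33. Mllt11 rose at 1.16, though it overlaps Cdc42se1, Tnf at 0.82 (adjusted p = 0.00515), Rps23 at 0.32, Atp5g3 at 0.28 and Psmb7 at 0.26. The values of Rpsa (9 named pseudogenes), Rps23 (2) and Psmb7 (1, and an overlap with Nek6) are uncertain.

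By edgeR with Benjamini-Hochberg adjustment over 9 footprint libraries, 689 of 9664 genes rose and 1373 fell. Without the 120 min lysate 3 rose and 64 fell, and the call was lost by mt-Atp8 (adjusted p = 0.0522), mt-Atp6 (0.151), Rps23 (0.13), Tnf (0.0587), Hspa8 (0.256), Atp5g3 (0.153), Psmb7 (0.211) and Cdc25a (0.0621). Their slopes kept their direction there, at 1.54, 1.34, 0.29, 1.07, -0.51, 0.27, 0.23 and -1.30. Hspa8 also lost it without the 20 min lysate of experiment 1 or 2 (0.053 and 0.077) or the 40 min lysate of experiment 1 (0.0517). Ribosomal protein genes rose in 48 of 75 cases and fell in 4, or 64 and 5 adjusted over the list alone (median 0.27, camera adjusted p = 4.29e-15, adjusted p = 0.117 with an estimated correlation). Oxidative phosphorylation genes rose in 37 of 74 cases, or 63 adjusted over the list alone (camera adjusted p = 2.98e-17, adjusted p = 0.117 with an estimated correlation). Proteasome subunits rose in 17 of 34 cases, or 26 adjusted over the list alone (camera adjusted p = 5.21e-09, adjusted p = 0.117 with an estimated correlation). Mitochondrially encoded mRNAs rose in 8 of 13 cases, or 10 adjusted over the list alone (median 0.95, camera adjusted p = 9.92e-09, adjusted p = 0.331 with an estimated correlation). Immediate-early regulators fell in 12 of 40 cases, or 14 adjusted over the list alone (median -0.51, camera adjusted p = 9.82e-06, adjusted p = 0.6 with an estimated correlation). Across 9187 genes, which are not independent replicates, the slopes in input and footprints correlated with r = 0.80 and rho = 0.79.

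The last comparison asked which genes changed their footprint to input ratio with time. edgeR with Benjamini-Hochberg adjustment called 0 of 10110 genes, with 241 at unadjusted p under 0.05, while DESeq2 called 9. Tnf came nearest, at 1.30 log2 per hour (SE 0.216, adjusted p = 0.0906). Its footprints went from 16.6 to 62.7 normalised CPM between 0 and 120 min of experiment 1 while its input went from 53.9 to 40.3. Rpsa was at -1.01 (adjusted p = 0.114), Rps2 at -0.82 (0.105), Pabpc1 at -1.69 (0.884) and mt-Atp8 at 1.59 (0.642). Input of Pabpc1 was uneven, at 2195 normalised CPM at 90 min of experiment 1 against 450 to 720 at its other times. In experiment 2 it was 1715, 1623 and 655 at 20, 30 and 40 min, so the ratio slope of Pabpc1 is uncertain. Rpsa has 9 and Rps2 11 named pseudogenes, and without label Rps2 held 0.837% converted reads in footprints and 0.903% in input, so both are uncertain. Tnf passed with experiment as a replicate block (1.31, adjusted p = 0.00431), with lysate as a replicate block (1.33, adjusted p = 0.05), in experiment 1 alone (adjusted p = 0.0166) and without the 40 min lysate of experiment 2 (adjusted p = 0.0171). Rpsa and Rps2 passed with the experiment block (adjusted p = 0.0199 each) and in experiment 1 alone (0.0115 and 0.0337), but not with the lysate block (-1.04 and -0.84, adjusted p = 0.361 each). Without the unlabelled lysate all 3 passed (adjusted p = 0.0407 each). All 3 passed with DESeq2 (adjusted p = 2.49e-05 for Tnf, 0.000324 for Rpsa and 6.06e-05 for Rps2).

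**Figure D4:**
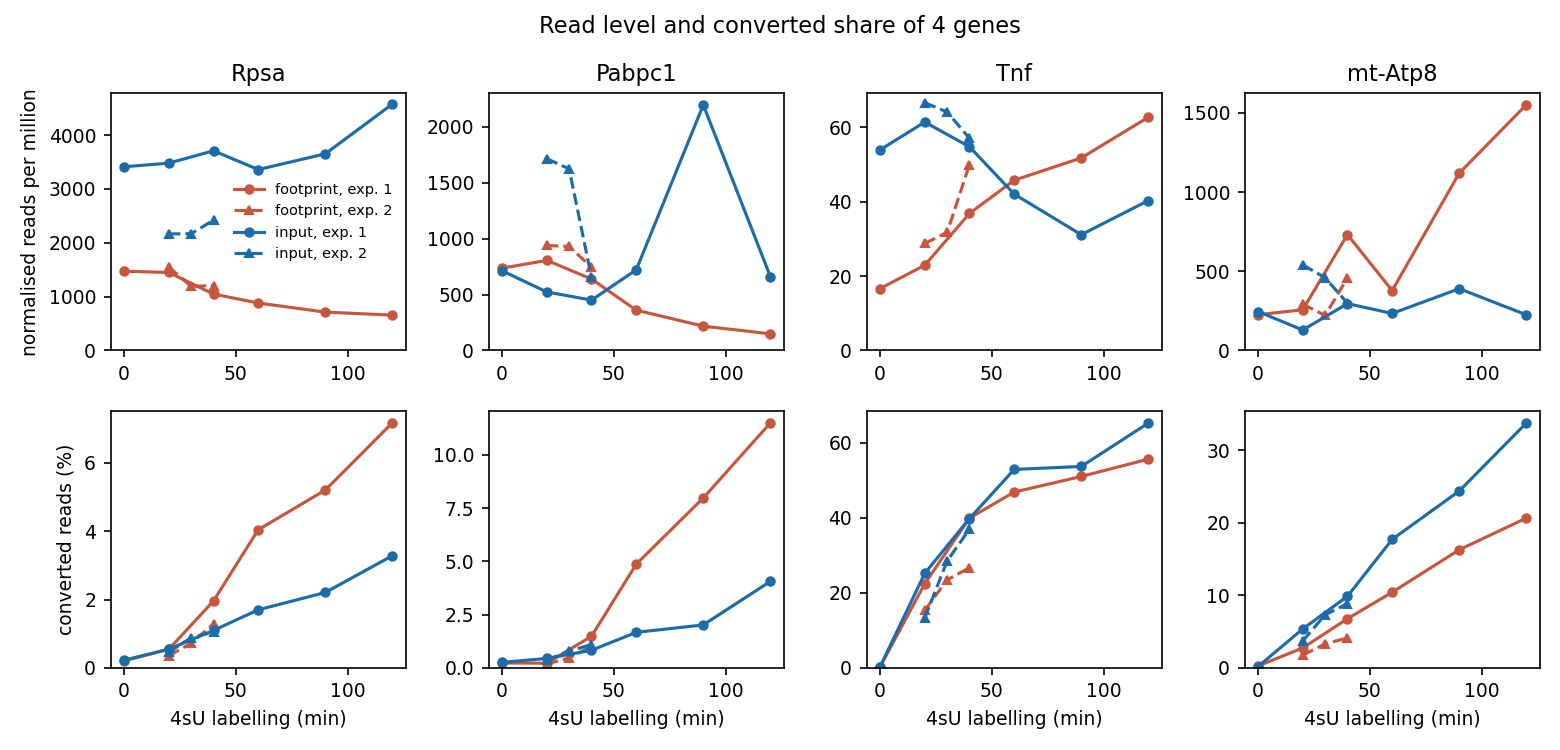
Normalised CPM (top) and converted reads in % (bottom) against 4sU labelling time (min) for Rpsa, Pabpc1, Tnf and mt-Atp8, 1 point per library, in input and footprints of experiments 1 and 2. Footprints of Rpsa went from 1472 to 656 CPM in experiment 1 while their converted share went from 0.206% to 7.17%, against 3.28% in input.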

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

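The tests of error background, nuclear RNA, later loading, less synthesis, the ribosomal protein mRNAs, the 9 other genes with a higher share and the splits of the ratio trend were chosen after the result was seen.

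The largest departure from what the comparison as a whole showed was in the mitochondrially encoded mRNAs. Although no gene passed in the trend of the footprint to input ratio, all 13 of these mRNAs had a positive slope, with a median of 1.10 log2 per hour. Camera put the list upward with adjusted p = 1.63e-28, and adjusted p = 0.0355 with an estimated correlation. Adjusted over the list alone, 9 of 13 passed by edgeR. These 13 mRNAs are not independent replicates. The camera adjusted p = 1.63e-28 and all counts of members given here thus overstate the evidence. Only the camera value with an estimated correlation, adjusted p = 0.0355, allows for shared movement within the list. The median was 1.67 without the unlabelled lysate, 0.90 without the 120 min lysate, 0.86 without the 20 min lysate of experiment 2 and 0.70 in experiment 1 alone, with 13 of 13 above 0 each time. Input of mt-Nd2 was high at 20 and 30 min of experiment 2 (1200 and 951 CPM, against 203 to 549 CPM in experiment 1). That of mt-Nd5 was too (1920 and 1620, against 313 to 898 CPM). Input of mt-Co3 was not (6194 and 5945, against 6143 to 8931 CPM), but its footprints were low there (318 and 179, against 464 to 1612 CPM). Both patterns add to the slope over both experiments. Recovery of mitochondrial ribosomes in the monosome fraction was not tested.

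In the same comparison camera called 4 further lists with a correlation of 0.01, and none with an estimated one (adjusted p = 0.934 with an estimated correlation for each). These were ribosomal protein genes (adjusted p = 0.0240; median -0.02, but 0.12 in experiment 1 alone), immediate-early regulators (adjusted p = 0.0240; median 0.21), histone genes (adjusted p = 0.0277; median 0.12) and inflammatory genes (adjusted p = 0.0313; median 0.05). By edgeR 4 ribosomal protein genes fell, and 2 inflammatory genes rose and 1 fell, when adjusted over the list alone. The cause was not tested for any of these lists.

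The lower converted share in footprints may have more than 1 source. Reads matched for T content still gave a mean log2 odds ratio of -0.927 ± 0.46 (SD, n = 8), weighting genes equally in both materials gave -0.682 ± 0.38, and reads with at least 2 conversions, rarely made by sequencing errors, gave -1.84 ± 0.96, so none of these removes it. Poorer chemical conversion in footprints would lower the conversion probability, which was 0.548 to 0.914 of that in input in 7 of 8 lysates, but the log2 ratio of labelled-read shares from the mixture stayed lower at -1.60 over 8 lysates and -1.004 ± 0.91 over those 7. Later loading of new mRNA onto ribosomes could give a log2 odds ratio nearing 0 with time. After background subtraction rho was 0.928 (exact p = 0.00218) and r 0.66 (exact p = 0.0715) over 8 lysates. Without the 2 farthest lysates rho was 0.883 (exact p = 0.0444). These p-values ignore that experiment 2, with lower ratios, was labelled for 20 to 40 min only. Experiment 2 had no unlabelled lysate, so the unlabelled share of experiment 1 was subtracted from it. Its 20 min footprints held 0.313% converted reads against 0.298% subtracted. That left 0.015% and the lowest log2 odds ratio of the 8, at -5.09, so rho rests partly on a value near the floor. Labelled nuclear RNA leaking into input is a candidate explanation for which 0 intronic or nuclear values were measured here, so later loading and nuclear RNA both remain open.

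The falling input slopes could reflect loss of labelled reads in alignment or less synthesis during labelling. If converted reads failed to align, falling genes should fall less in reads with few T positions, and the median slope there (at most 4 T) was 0.820 of that in reads with at least 9 T in input (95% bootstrap interval 0.779 to 0.866, 391 genes) and 0.841 in footprints (0.809 to 0.880, 1012 genes), which leaves this open. Less synthesis would make fast-turnover mRNAs fall most, and across 7023 genes, which are not independent replicates, relative labelling and input slope correlated at rho = -0.636. It was -0.656 without the 120 min lysate, -0.612 in experiment 1 and -0.584 for footprint slopes. Loss of labelled reads would predict this too, so the correlation does not part the explanations.

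Relative to the library-wide share, 59 of 71 ribosomal protein genes had a higher converted share in footprints by edgeR (median 0.49), though camera did not call the group in the unscaled shares (adjusted p = 0.0623). Background errors do not account for it, as the median was 0.564 in reads with at least 2 conversions, but immediate-early (0.91), histone (0.91), inflammatory (0.73) and mitochondrially encoded mRNAs (0.69) stood higher there, so it is not particular to this group. Strain variants do not account for Rpsa, Pabpc1 and Fth1, whose unlabelled footprints held at most 0.227% converted reads against 0.298% in the library. But the unscaled excess of Rpsa and Pabpc1 over input was absent in reads with at least 2 conversions (0.05 and -0.07). It was also absent in the fit of experiment 2 (-0.13 and -0.62), which ended at 40 min, although Rpsa was higher at that time (1.28% against 1.05%). The library-wide mean log2 odds ratio was lower there too, at -1.84 with at least 2 conversions and -1.46 in experiment 2, against -0.97. Both genes thus still stood above the library-wide value in each case. At 20 min of experiment 1 neither gene had an excess (Rpsa 0.545% against 0.546%, Pabpc1 0.219% against 0.441%). Labelling time may thus enter the contrast between the experiments. Loss of older footprints of ribosomal protein mRNAs might raise the new share. Across 71 of these genes the slope of the footprint to input ratio and the relative conversion correlated at rho = -0.359 (permutation p = 0.0022). The genes are not independent replicates, which the permutation ignores. Without Rpsa, Rps2, Rpl12 and Rplp0 rho was -0.249, and across 8276 genes it was -0.139. Both measures come from the same footprint reads, so they share errors and the correlation cannot decide this. For the other 9 of the 12 genes with a higher share, 9 of 9 had more converted reads in unlabelled footprints than the library, such as 53.6% in AC155163.2, 10.2% in Gpn2 and 1.65% in Gnai2, so sequence variants or misaligned reads may account for them, which the values do not part, as unlabelled input also exceeded the library in Tmem8 (6.25%), Gpn2 (2.86%), Mcph1 (1.64%), Xxylt1 (1.44%), Clip1 (1.34%), Nab1 (1.05%) and Gnai2 (0.504%), while AC155163.2 held 0 of 27 converted reads there.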

How the results depend on the processing

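Of the settings below, experiment 2 alone, conversion relative to the library-wide share, reads with at least 2 conversions and conversions per T position were chosen after the result was seen. For input slopes DESeq2 called 1309 genes (338 up and 971 down, with 646 of the 647), experiment as a replicate block 1540 (384 up and 1156 down), and leaving out 1 lysate gave 0 (without 120 min) to 838. For footprint slopes leaving out 1 lysate gave 67 (without 120 min; 1529 at unadjusted p under 0.05) to 2371 genes, and no low-count filter gave 271 up and 1436 down. For the ratio trend DESeq2 called 9 genes (3 up and 6 down), the experiment block 3, the lysate block 1, experiment 1 alone 3 and leaving out 1 lysate 0 to 6. For conversion in footprints experiment 1 alone gave 2021 genes, relative conversion 1104 (836 higher and 268 lower), at least 2 conversions 2290, both together 456 (295 higher and 161 lower), and leaving out 1 lysate 3455 to 5311. Relative labelling with at least 2 conversions gave 1720 genes, and leaving out 1 lysate 4368 to 5044. From conversions per T position it gave 4956, of which 4611 were shared with the fit as planned, all in the same direction. For footprints against input leaving out 1 lysate gave 7533 to 7707 genes, the experiment block 8066, and DESeq2 size factors 3926 up and 3849 down with a median of 0.02 in place of -0.04. For this comparison, the input and footprint slopes and the ratio trend, only the 0, 20, 40 and 120 min lysates were left out. Their ranges thus do not cover the lysates of 30, 60 and 90 min. The trend of the log2 odds ratio had r = 0.75 with at least 2 conversions (exact p = 0.0253) and 0.62 to 0.76 on leaving out 1 lysate. The mean log2 odds ratio was -1.05 to -0.85 on leaving out 1 lysate. Leaving out 1 library gave r = 0.985 to 0.994 for input and 0.951 to 0.994 for footprints against time, and a median lag of 15.7 to 23.02 min. Camera's 48 calls of 108 fell to 1 with an estimated correlation. In conversion, experiment 2 alone reversed Rpsa (-0.13) and Pabpc1 (-0.62), and at least 2 conversions reversed Pabpc1 (-0.069) and Gnai2 (-0.55). Among the genes named, both replicate blocks made Cd79b (footprints against input, which passed in other settings too) and Tnf (ratio trend) pass, the experiment block alone made Rpsa and Rps2 (ratio trend) pass, and these blocks changed no other call, and the cause of these shifts was not tested.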

Other observations

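The grouping of genes by relative labelling and the test of density against turnover were chosen after the result was seen.

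Slowly and rapidly labelled mRNAs parted in their relative levels. Among 5 groups of nearly equal size, the least labelled had a median input slope of 0.14 ± 0.13 log2 per hour (SD over 1409 genes) and the most labelled -0.35 ± 0.29 (SD over 1388 genes). In footprints the medians were 0.15 ± 0.14 (1409 genes) and -0.30 ± 0.37 (1395 genes). Herpud1, Insig1, Dnajb1, Hk2 and Aurka, which belong to lists that were otherwise mixed or weakly labelled, stood above the input median at 2.72, 2.30, 2.11, 2.01 and 1.53 by limma. No background was subtracted, and without label Herpud1 held 2.23% and Hk2 1.48% converted reads in input, against 0.289% in the library.

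Rapid turnover might go with sparser ribosomes. Across 7044 genes, which are not independent replicates, relative labelling and footprint density correlated at rho = -0.133, a weak relation that leaves this open. A count of reads over coding regions alone could part it from reads in untranslated regions.

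Splits of the libraries were counted too, but they cannot show how much of each count comes from sample structure. Among 60 splits in which every lysate was parted, the real one included, the real split ranked 1 of 60 for footprints against input (7699 genes, highest other 5607) and 1 of 60 for conversion (4924, highest other 3693). The other splits swap the materials in some lysates, so those swapping few keep most of the difference. Those swapping more put it into the spread between libraries and call few or no genes. Both ranks of 1 were thus largely set by the way the splits were made, and they are uninformative. For the ratio trend the real split called 0 genes, so 60 of 60 splits called as many by necessity and the ranking is uninformative. Of the other splits 4 called any gene, with a highest of 6179. A further 20 splits per comparison that did not part every lysate gave 0 genes at most, with the same limit.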
